A study of Mus musculus with 2 samples.

How the data were processed

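The series compared the RNA of mouse pro-B cells with a deleted Setdb1 gene (Setdb1 Δ/Δ) with that of cells carrying undeleted alleles (Setdb1 C/C). Setdb1 encodes a histone H3 lysine 9 methyltransferase, and pro-B cells are B cell precursors of the bone marrow. Per the labels' protocols, pro-B cells were sorted by flow cytometry from bone marrow and kept in culture with interleukin 7 (IL-7) at 5 ng/µl until day 4. The cells of both groups carried a bcl2 transgene. Total RNA was freed of ribosomal RNA and made into 101 bp paired-end libraries, which were pooled for sequencing. Each group had 1 library, so no difference has a replicate check, and no p-value is given. The labels give no sex, age or strain for the animals, and they do not say which exons the deletion removes.

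The deposited table held 93615 Ensembl transcripts with 1 RPKM value (reads per kilobase of transcript, scaled to library depth) per library, which the authors had rounded to 3 decimals. Its columns were headed Wt and Del. They were read as C/C and Δ/Δ, the only match the labels allow. The submitters' processing notes name TopHat2 2.0.9 and bedtools, and the builds mm9 and mm10. Which build this table used, its annotation release and any strand setting are not given in the sources used here. The library kit, per the labels, does not mark strand, so reads of a gene and of an antisense partner cannot be told apart. The columns summed to 2165867 RPKM in C/C and 2013062 RPKM in Δ/Δ, and how reads shared by overlapping transcripts were counted is not given. Reads from near-identical copies (processed pseudogenes, histone genes, immunoglobulin segments, globin genes, mitochondrial sequences with nuclear copies) can be placed on either copy, and values of such genes are uncertain.

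Depth was recovered from the values. An RPKM value multiplied by the exonic length of its transcript in GENCODE M21 (GRCm38) was a whole multiple of a step that differed between the columns. The steps gave 170.6 M reads for C/C and 193.3 M for Δ/Δ. Of the low values of transcripts of 100 to 800 bases, 95.8% in C/C and 95.2% in Δ/Δ lay within 0.1 of a whole read. The search was tested on simulated data of 3 known depths and missed them by at most 0.008%. More transcripts had 2 reads than 1 read (662 against 601 in C/C, 750 against 540 in Δ/Δ), so mates appear to have been counted separately. Intervals of single genes therefore took 2 reads as 1 fragment. They are exact 95% intervals of the ratio of 2 Poisson rates and cover counting error only. Ranges of medians or shares over resampled genes, in the closing sections, hold the middle 95% of resamplings. They show the spread among genes of these 2 libraries, and genes are not replicates. At these depths 3 reads on a transcript of 2 kilobases correspond to 0.00879 RPKM in C/C and 0.00776 RPKM in Δ/Δ.

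Transcript identifiers were matched to GENCODE M21 symbols, which succeeded for 89571 transcripts (95.7%). The other 4044 transcripts had no gene name and entered no comparison. For each of 36980 symbols the transcript of highest mean RPKM stood for the gene. A gene was called measured at 1 RPKM or more in at least 1 library, which 12556 genes met, 10750 of them protein-coding. Coordinates are those of GRCm38 from the same annotation, because the table holds none.

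The comparison used log2((Δ/Δ + 0.5) / (C/C + 0.5)) with RPKM as deposited. This understates the change of genes near 0. A fixed rule of size took the place of a test, and a gene is called higher or lower in Δ/Δ when this value was at least 1 or at most -1, a change of at least 2-fold on that scale. Fold values given beside RPKM are plain ratios without the added 0.5. Gene lists for 20 pathways, cell types and complexes, and 8 families defined by symbol, were fixed before the data were examined. For a list of at least 5 measured members, the median log2 ratio was placed among 10000 random lists of the same size drawn from 20 bins of mean expression. A list is said to stand apart below percentile 2.5 or above percentile 97.5. Such a percentile describes these 2 libraries and is not a p-value.

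Genes named in the text followed a rule also fixed in advance. It takes Setdb1 and Bcl2, then the 12 highest and 12 lowest log2 ratios among genes that passed the size rule with 5 RPKM or more in at least 1 library, and up to 4 members of each list with the largest absolute log2 ratio. Gene models without a proper name, nuclear small RNA genes, pseudogenes named as such and immunoglobulin or T cell receptor segments were left out of the 12. Genes named outside this rule are marked as chosen after their values were seen.

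The counting and list steps were tested on simulated reads drawn for 22710 genes from the 2 libraries' means and depths, with 200 genes changed. The size rule recovered 98% of genes raised 2.5-fold, 100% of those raised 4-fold, 91.8% of those lowered to 0.4 of their level and 98% of those lowered to 0.25. Among 12046 unchanged measured genes, 5 passed as higher and 5 as lower.

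The alternatives were pseudocounts of 0.1 and 1 RPKM, no filter or a filter of 5 RPKM, size rules of 1.5-fold and 4-fold, and matching in 5 bins. Others were 3 other scalings (centring on the median, a common RPKM sum, and that sum without the 20 most abundant genes) and the mean over a symbol's transcripts. Added after the data were seen were autosomal genes only, protein-coding genes only, a count without pseudogenes, histone and mitochondrial genes, and the transcript with the most reads. Copies of processed pseudogenes were sought with BLAST+ 2.17.0 against annotated coding transcripts, and similar proteins of adjacent genes with the same program. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, Biopython 1.88 and matplotlib 3.10.9. Endogenous retroviral elements as such were not analysed here, since the table lists annotated transcripts.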

Results

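RNA was sequenced from 2 cultures of mouse pro-B cells, 1 with undeleted Setdb1 alleles (Setdb1 C/C) and 1 with the gene deleted (Setdb1 Δ/Δ). Both cultures carried a bcl2 transgene and had grown for 4 days with IL-7. SETDB1 is a histone H3 lysine 9 methyltransferase that works with the co-repressor TRIM28 to silence retroviral sequences. The libraries held 170.6 M reads (C/C; M, mega) and 193.3 M reads (Δ/Δ), as recovered from the RPKM values. With 1 library per genotype, every difference below is a difference between these 2 libraries and has no replicate check. The intervals given for single genes cover counting error only. The libraries also differed in sex markers, which stand at the end with their values, so genotype and sex cannot be separated for any gene.

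The first question was whether the deleted gene itself differed. Setdb1 (ENSMUST00000107171, GRCm38 chromosome 3, 95323525 to 95357202, minus strand) measured 17.0 RPKM in C/C and 12.6 RPKM in Δ/Δ. The ratio of Δ/Δ to C/C was 0.743, with a 95% counting interval of 0.717 to 0.770, from 13243 and 11148 reads. Across the 6 listed Setdb1 transcripts the ratio ran from 0.742 to 0.853. The log2 ratio of -0.41 did not pass the size rule. These are values over whole transcripts. Transcripts that lack only some exons still give reads over the rest, so the value cannot show how complete the deletion was. Bcl2, the anti-apoptotic gene that both cultures also carried as a transgene, measured 10.5 RPKM in C/C and 5.47 RPKM in Δ/Δ, a log2 ratio of -0.88. That value cannot separate RNA of the transgene from RNA of the cells' own gene, so it is not a measure of the transgene.

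Of 12556 measured genes, 788 were higher and 836 were lower in the Δ/Δ library by the size rule. Counting noise alone put 5 of 12046 simulated unchanged genes above the rule and 5 below it. The median log2 ratio of all measured genes was -0.09. Among protein-coding genes 594 were higher and 531 lower. Which direction held more genes depended on the scaling, with 906 higher and 728 lower after centring on the median, and a 4-fold rule left 220 higher and 234 lower.

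**Figure D1:**
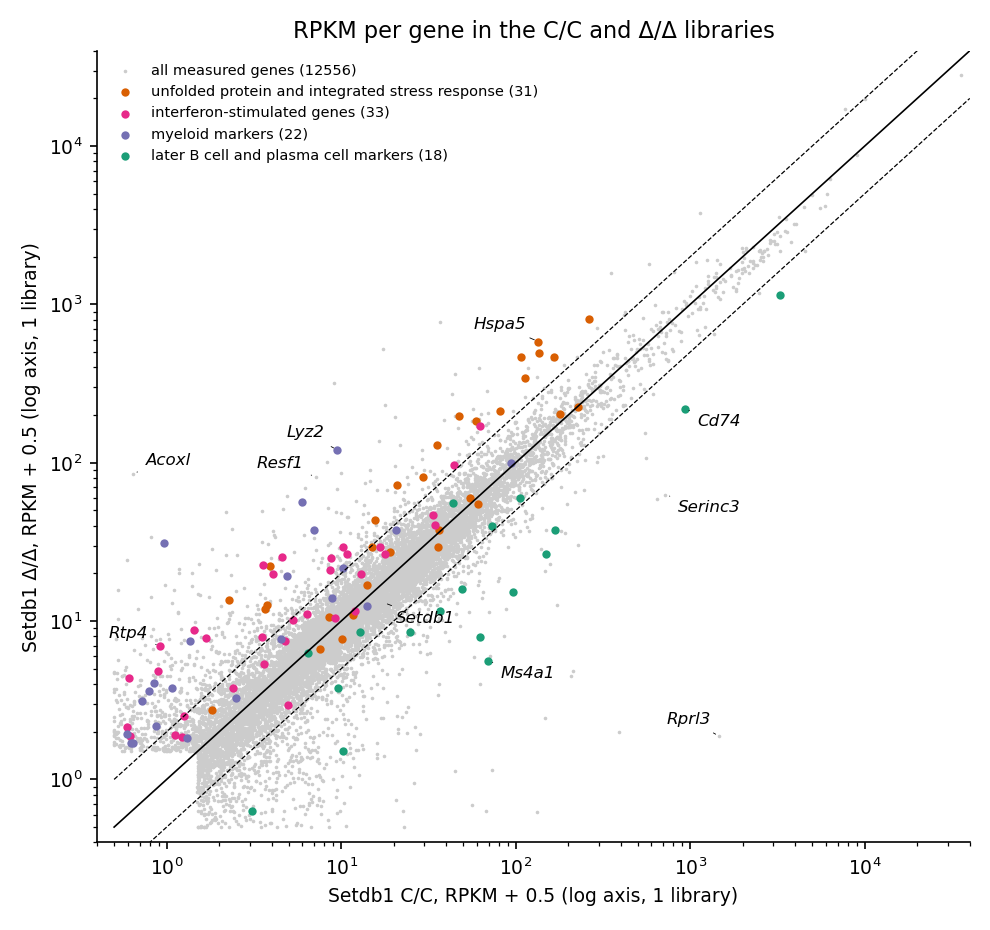
RPKM plus 0.5 of the 12556 measured genes in the C/C library (horizontal, log axis) and the Δ/Δ library (vertical, log axis), 1 point per gene. The solid line marks equal values and the dashed lines the 2-fold size rule on that scale; 4 gene lists are coloured, with stress response, interferon-stimulated and myeloid genes mostly above the lines and later B cell genes mostly below.

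Genes that help proteins fold in the endoplasmic reticulum were higher in Δ/Δ. Hspa5, which encodes the chaperone BiP, measured 134 RPKM in C/C and 582 RPKM in Δ/Δ, a ratio of 4.34 (interval 4.24 to 4.45). Hsp90b1, the chaperone GRP94, went from 107 to 466 RPKM. Ern1, which encodes the stress sensor IRE1α, was 7.39-fold higher at 13.1 RPKM, and Derl3, a factor that helps remove misfolded proteins, was 6.41-fold higher at 21.8 RPKM. In the fixed list of the unfolded protein and integrated stress response, 17 of 31 measured members were higher and 0 were lower. The list's median log2 ratio was 1.47, at percentile 100 of the random lists. Of further members, all chosen after their values were seen, the chaperones and folding enzymes Calr (263 to 806 RPKM), Pdia6 (135 to 491 RPKM) and Hyou1 (47.1 to 198 RPKM) passed the rule. So did Xbp1 (58.5 to 183 RPKM), the transcription factor activated by IRE1α. The integrated stress response genes Atf4 (178 and 204 RPKM), Ddit3 (35.3 and 29.0 RPKM), Trib3 (8.03 and 10.1 RPKM) and Asns (54.3 and 59.5 RPKM) did not, and neither did some genes of protein degradation and stress sensing in the endoplasmic reticulum, among them Herpud1 (226 and 225 RPKM), Syvn1 (60.3 and 54.3 RPKM), Edem1 (14.6 and 29.0 RPKM, past the rule after centring) and Atf6 (11.2 and 10.4 RPKM). Markers of myeloid cells and mitochondrial and small nucleolar RNA genes were also higher in this library (below), and Xist was measured almost only there.

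Interferon-stimulated genes were also higher in Δ/Δ. Ifi44, an interferon-induced gene, measured 3.08 RPKM in C/C and 22.1 RPKM in Δ/Δ, a ratio of 7.18 (interval 6.03 to 8.65). Usp18, a negative regulator of interferon signalling, was 8.87-fold higher at 8.34 RPKM. The transmembrane protein transporter gene Rtp4 (0.417 to 6.45 RPKM) and Oas3 (0.106 to 3.89 RPKM), which makes the activator of RNase L, started from low levels. Of 33 measured members of the list, 18 were higher and 0 lower, with a median of 1.12 at percentile 100. The type I interferon gene Ifnb1, also chosen after its value was seen, was listed at 0 RPKM in both libraries. Myeloid and dendritic cell markers were higher in the same library (below). Among the genes for retrovirus restriction and receptors, 4 of 24 were higher and 2 lower, and the median of 0.21 lay at percentile 99.5. Tlr7, an X-linked sensor of single-stranded RNA, measured 1.01 RPKM in C/C and 14.4 RPKM in Δ/Δ. Trim30a went from 8.21 to 24.5 RPKM and Trim30d from 3.89 to 9.85 RPKM, whereas Tlr9, a sensor of unmethylated DNA, was lower (2.68 to 0.714 RPKM). Trim30a and Bst2 belong to both of these lists. The 6 measured members of the list of annotated genes of retroviral origin had a median of -0.77 at percentile 1.74, and 1 of them, Arc, was lower (2.78 to 0.610 RPKM). Without the filter on low values that median was -0.08, at percentile 7.6. Rtl8a (1.30 and 0.454 RPKM), the restriction gene Fv1 (3.70 and 1.80 RPKM) and Rtl5 (3.83 and 2.21 RPKM) did not pass the size rule.

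B lineage genes were lower as a group, but not all of them. Ly6d, a surface marker of B-committed progenitors, measured 643 RPKM in C/C and 58.6 RPKM in Δ/Δ, 10.98-fold lower. The ectoenzyme gene Cd38 was 4.83-fold lower, the transcription factor gene Ikzf3 (Aiolos) 4.72-fold lower, and the recombinase gene Rag1 4.12-fold lower at 6.64 RPKM. Of 40 measured members, 12 were lower and 1 was higher, with a median of -0.59 at percentile 0. Some members, chosen after their values were seen, went another way. Vpreb2, a surrogate light chain gene, was the higher member (421 to 894 RPKM). Vpreb1 (745 and 893 RPKM), Igll1 (785 and 766 RPKM) and Dntt (142 and 256 RPKM), which encodes terminal transferase, stayed within the size rule. Pax5, the B lineage commitment factor, lay at the edge of the rule at 201 and 97.49 RPKM (log2 ratio -1.04, and -0.95 after centring), Cd79a, a signalling chain of the B cell receptor, went from 548 to 153 RPKM, and the transcription factor gene Ebf1 measured 129 and 76.9 RPKM. Myeloid, dendritic and erythroid markers were higher in the same library (below). A lower share of B lineage cells alone would lower B lineage genes by a common factor, and the members above did not change alike. How much such a share adds to the change of these genes, or of those of later B cells, was not tested.

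Genes of later B cells were lower still. Ms4a1, which encodes CD20, measured 69.3 RPKM in C/C and 5.07 RPKM in Δ/Δ, 13.7-fold lower. Ciita, the master regulator of class II histocompatibility genes, was 9.67-fold lower, H2-Eb1, one of its targets, 6.46-fold lower, and the adhesion gene Cd2 8.36-fold lower. In that list of later B cell and plasma cell markers 13 of 18 measured members were lower and 0 higher, with a median of -1.64 at percentile 0. The immunoglobulin µ constant gene Ighm, a member of the list chosen after its value was seen, went from 3274 to 1143 RPKM. Immunoglobulin V segments behaved alike. Of 86 measured heavy chain V segments 77 were lower and 1 higher, with a median of -2.25, and of 82 light chain genes 71 were lower and 1 higher, with a median of -2.19. Both medians lay at percentile 0. The 4 light chain genes listed at 0 in 1 library make the latter -2.30 when set at their counting bound. The heavy chain segments with the largest change were Ighv2-9 (12.2 to 0.562 RPKM), Ighv1-66 (7.16 to 0.177 RPKM), Ighv3-6 (20.7 to 1.57 RPKM) and Ighv1-9 (9.63 to 0.550 RPKM). Among light chain genes they were Igkv4-57 (7.199 to 0.103 RPKM), Igkv3-12 (25.97 to 1.64 RPKM), Iglv2 (23.3 to 1.47 RPKM) and Igkv4-50 (8.81 to 0.279 RPKM). Reads of V segments can be shared between close relatives, so single segments are uncertain. The family of symbols for class I histocompatibility genes had 2 higher and 5 lower genes of 18, with a median of -0.09 at percentile 47.0 that was 0.00 after centring. That symbol pattern also takes in the class II chaperone genes H2-DMb2 (57.6 to 5.47 RPKM), H2-DMb1 (20.4 to 2.01 RPKM) and H2-DMa (21.7 to 4.49 RPKM), which were lower. The non-classical class I gene H2-Q7 was higher (9.50 to 47.9 RPKM).

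Markers of other blood cell types were higher in the Δ/Δ library. Lyz2, lysozyme of macrophages and neutrophils, measured 9.01 RPKM in C/C and 120 RPKM in Δ/Δ, 13.3-fold more (interval 12.5 to 14.2). The calgranulin genes S100a8 (0.463 to 30.8 RPKM) and S100a9 (5.44 to 56.2 RPKM) and the Fc receptor gene Fcer1g (0.869 to 6.95 RPKM) were higher too. Of 22 measured myeloid markers 15 were higher and 0 lower, with a median of 1.58 at percentile 100. Dendritic cell markers had 5 of 6 higher and 0 lower (median 1.97, percentile 100), led by Klk1 (0.0540 to 2.10 RPKM), Siglech (0.850 to 5.64 RPKM), Ccr9 (0.116 to 1.92 RPKM) and Clec10a (0.173 to 2.12 RPKM). Erythroid and megakaryocyte markers had 7 of 9 higher and 0 lower (median 2.23, percentile 100). These included the globin genes Hbb-bs (3.60 to 34.5 RPKM), Hba-a1 (1.84 to 19.01 RPKM) and Hba-a2 (1.25 to 13.7 RPKM), of which the last 2 are near-identical copies, and the platelet chemokine gene Ppbp (0.0430 to 2.07 RPKM). Several of these members reached 1 RPKM in Δ/Δ alone, and without the filter on low values the medians were 0.44 for dendritic and 0.52 for erythroid and megakaryocyte markers. T lineage markers did not stand apart, with 2 higher and 1 lower of 8 and a median of 0.34 at percentile 95.8. Cd4 (0.150 to 2.62 RPKM) and Thy1 (23.7 to 55.7 RPKM) were higher and Lat (75.7 to 36.3 RPKM) lower, though Lat was short of the rule after centring (log2 ratio -0.95), while Zap70 measured 2.06 and 0.933 RPKM. Stem and progenitor markers had a median of -0.72 at percentile 0.21 over 8 members, of which Satb1 was lower (23.0 to 9.01 RPKM) and Ly6a (Sca-1) higher (1.32 to 28.1 RPKM). Kit (4.42 and 2.24 RPKM) and Mycn (10.2 and 5.27 RPKM) did not pass the rule, and the mean of the list was -0.05. Without the filter on low values the median was -0.02, at percentile 54.4. Fewer than 5 markers of NK cells (0 measured), mast cells (2) and stroma (3) reached 1 RPKM. Of these the protease gene Prss34 (listed at 0 in C/C, 1.16 RPKM in Δ/Δ), Cd63 (0.562 to 5.38 RPKM) and Timp3 (0.460 to 2.93 RPKM) were higher, and Ccl3 (0.926 and 1.18 RPKM) and Pecam1 (30.4 and 18.2 RPKM) were not. Over members with at least 20 reads in total, the median log2 ratio of read density was 2.55 for 13 NK, 2.99 for 9 mast cell, 0.58 for 20 stromal and 2.87 for 33 myeloid markers.

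**Figure D2:**
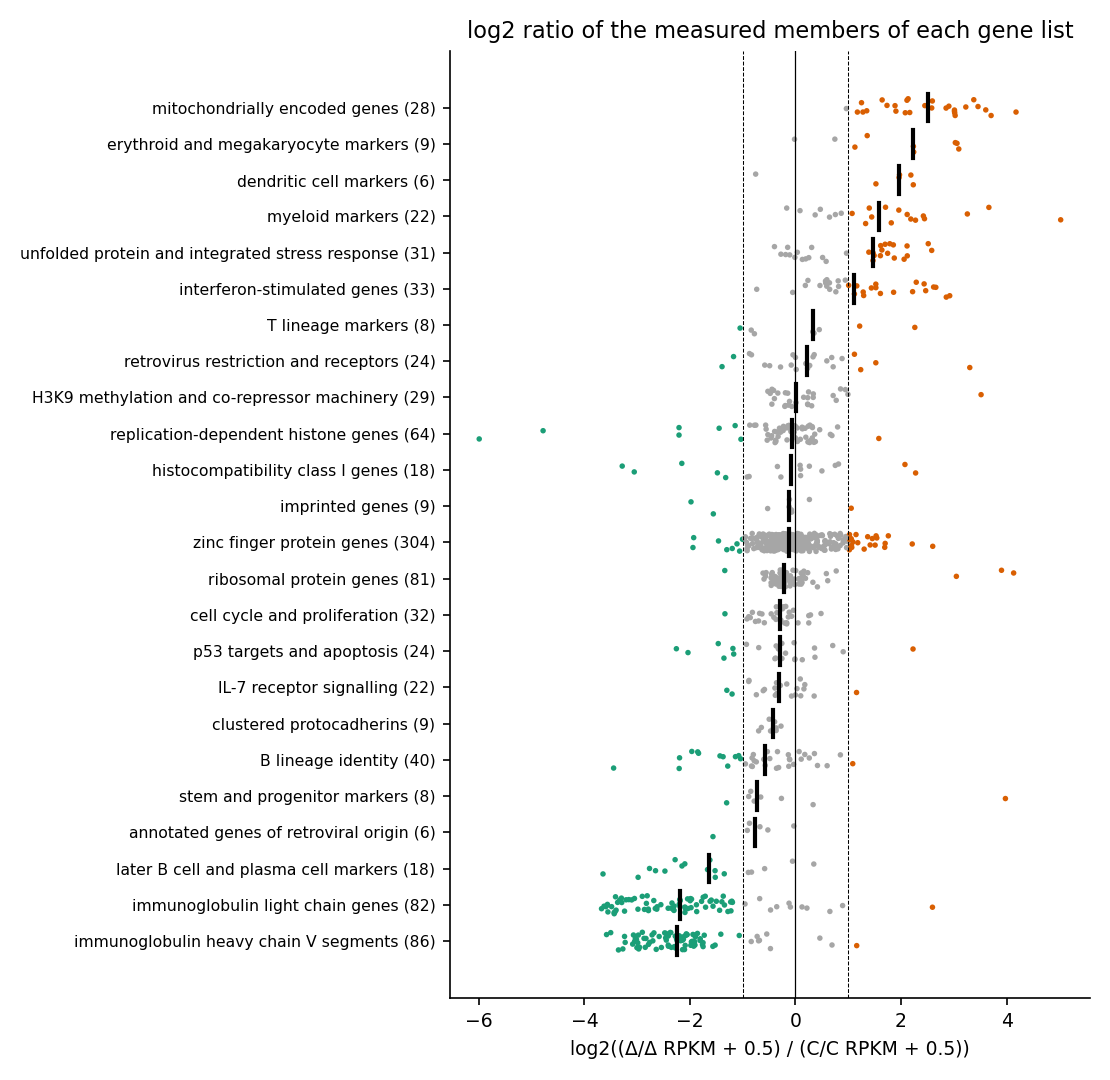
Log2 ratio of Δ/Δ to C/C RPKM, each plus 0.5, for every measured member of the 24 lists and families with at least 5 measured members (1 point per gene, 1 library per genotype). Black bars are list medians, dashed lines the size rule, and the number of members stands in brackets; medians run from -2.25 for heavy chain V segments to 2.52 for mitochondrially encoded genes.

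Single genes of the BCL2 family of apoptosis regulators passed the rule in either direction, and others did not pass it. Bcl2l1, which encodes the survival protein BCL-XL, measured 53.8 RPKM in C/C and 10.9 RPKM in Δ/Δ, 4.95-fold lower. Bcl2l11, which encodes the death-promoting protein BIM, went the other way, from 19.8 to 94.4 RPKM (ratio 4.78, interval 4.48 to 5.09). Bbc3 (PUMA), also death-promoting and a p53 target, was 4.25-fold lower at 10.7 RPKM, and the p53 target Zmat3 was 3.87-fold lower. Bax (150 and 78.7 RPKM), Mcl1 (168 and 110 RPKM) and Bid (14.4 and 23.8 RPKM), chosen after their values were seen, stayed within the rule. Cdkn1a (10.9 to 4.57 RPKM), Phlda3 (13.7 to 5.03 RPKM) and Btg2 (82.0 to 35.8 RPKM), chosen likewise, were lower. Of 24 measured p53 targets and apoptosis genes 1 was higher and 6 lower, and the median of -0.29 at percentile 4.58 did not stand apart. It did with a pseudocount of 0.1 RPKM (-0.34, percentile 2.36). IL-7 receptor signalling genes had 1 higher and 2 lower of 22, with a median of -0.32 at percentile 2.87. The insulin receptor substrate gene Irs2 (8.29 to 3.07 RPKM) and the phosphatase gene Dusp6 (5.55 to 2.13 RPKM) were lower, and Cish (6.22 to 14.5 RPKM), a STAT5 target, was higher. Cell cycle genes had 1 lower of 32, E2f2 (59.3 to 23.2 RPKM), and a median of -0.28 at percentile 1.30. Ccne1 (33.5 and 17.5 RPKM), Aurkb (123 and 66.5 RPKM) and Top2a (411 and 227 RPKM) did not pass the size rule.

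Of the genes of the H3K9 methylation and co-repressor machinery, 1 was higher by the rule as fixed. Resf1, the retroelement silencing factor that binds SETDB1, measured 6.64 RPKM in C/C and 81.2 RPKM in Δ/Δ, 12.2-fold higher (interval 11.8 to 12.7). Atrx (12.1 and 24.6 RPKM), Atf7ip (12.2 and 24.0 RPKM), which encodes a SETDB1 partner, and Cbx3 (68.6 and 124 RPKM) stayed within the rule, although Atrx (log2 ratio 1.09) and Atf7ip (1.04) passed it after centring, and the median over the 29 measured members was 0.01 at percentile 82.6. Zinc finger protein genes, many of which recruit TRIM28 and SETDB1 to repeats, had 22 higher and 8 lower of 304, and a median of -0.13 at percentile 29.4. Zfp983 (1.56 to 11.96 RPKM) and Zfp52 (1.47 to 8.64 RPKM) were the most raised, and Zfp827 (5.69 to 1.11 RPKM) and Zfp318 (6.42 to 1.32 RPKM) the most lowered. At a filter of 5 RPKM the family's median was -0.30, at percentile 0.01.

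All 4 measured germline genes were higher, of 40 on the list, and each reached the filter of 1 RPKM in Δ/Δ alone. Of the 17 members with at least 20 reads in total, 14 were at least 2-fold higher and 1 lower in read density. Among all nuclear protein-coding genes with as many reads, 1422 of 13785 were higher and 1327 lower. Markers of NK, mast and myeloid cells were higher in the same library (above). Fkbp6 was listed at 0 in C/C and measured 1.99 RPKM in Δ/Δ, Rnf17 went from 0.0130 to 1.44 RPKM, Tdrkh from 0.557 to 1.84 RPKM, and Rpl39l, a testis form of a ribosomal protein, from 0.309 to 13.7 RPKM. Imprinted genes had 1 higher and 2 lower of 9, with a median of -0.11 at percentile 48.5. The non-coding RNA gene H19 (148 to 37.2 RPKM) and Sgce (4.40 to 1.17 RPKM) were lower, Impact (2.27 to 5.25 RPKM) was higher, and Cdkn1c measured 1.16 and 0.651 RPKM. None of 9 measured clustered protocadherins passed the size rule (median -0.42, percentile 11.5); Pcdhgc4 (3.50 and 1.97 RPKM), Pcdhgc3 (4.02 and 2.39 RPKM), Pcdhgc5 (3.15 and 2.08 RPKM) and Pcdhga3 (3.07 and 2.07 RPKM) share exons and reads.

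Ribosomal protein genes had 3 higher and 1 lower of 81, with a median of -0.21 at percentile 0.72. The higher ones were relatives of the canonical genes, Rpl39l, Rps4l (1.03 to 22.3 RPKM) and Rpl22l1 (16.01 to 136 RPKM). Rps4l is annotated as a transcribed processed pseudogene. The lower one was the pseudogene Rps3a2 (25.1 to 9.62 RPKM). Replication-dependent histone genes had 1 higher and 7 lower of 64. Their median of -0.07 at percentile 44.4 turned to 0.02 after centring and to 0.01 with the common RPKM sum without the 20 most abundant genes. Hist2h2aa1 (72.2 to 0.643 RPKM), Hist1h2aj (25.8 to 0.456 RPKM), Hist2h3c2 (8.35 to 1.42 RPKM) and Hist2h2aa2 (6.56 to 1.03 RPKM) were lower, and all have close copies. Genes of the mitochondrial genome were higher in 27 of 28 cases, with a median of 2.52 at percentile 100. Examples are the complex I subunit gene mt-Nd3 (17.2 to 231 RPKM) and the transfer RNA genes mt-Tm (0.679 to 20.8 RPKM), mt-Tc (7.81 to 101 RPKM) and mt-Tn (4.13 to 50.4 RPKM). Reads of the mitochondrial genome made up 1.86% of the reads in C/C and 4.04% in Δ/Δ. Most of them lay on the ribosomal RNA gene mt-Rnr2, with 2728229 of 3.18 M in C/C and 6027980 of 7.81 M in Δ/Δ. That share thus mainly reflects ribosomal RNA left after its removal. Of 216 measured small nucleolar RNA genes, 65 were higher and 2 lower.

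The largest single increases included genes with no known role in B cells. Acoxl, an acyl-CoA oxidase-like gene that ends 2165 bases before Bcl2l11 on chromosome 2, measured 0.142 RPKM in C/C and 85.0 RPKM in Δ/Δ. That is 598-fold, with an interval of 384 to 997 set by 38 reads in C/C. Lalba, which encodes the milk protein α-lactalbumin, went from 0.312 to 33.5 RPKM, the phosphodiesterase gene Gdpd3 from 1.70 to 48.3 RPKM, the growth factor gene Nrg4 from 0.681 to 19.8 RPKM, and the tight junction gene Cldn4 from 1.87 to 37.4 RPKM. The lipase gene Lpl (0.185 to 11.4 RPKM) and the elastase gene Mmp12 (0.480 to 16.5 RPKM), both expressed by macrophages, were among them. St6galnac5, a sialyltransferase gene, had 3 reads in C/C and 1183 in Δ/Δ, a ratio of 348 with an interval of 72.0 to 2162. Serinc3, a membrane protein that restricts retroviruses, stood out among the decreases, at 721 RPKM in C/C and 62.1 RPKM in Δ/Δ, 11.6-fold lower (ratio 0.0861, interval 0.0831 to 0.0890). The IgM receptor gene Fcmr was 17.7-fold lower and the collagen gene Col5a3 70.1-fold lower at 0.133 RPKM. Rprl3, an RNase P RNA-like gene, went from 1468 to 1.37 RPKM, and Hmga1b from 26.5 to 1.05 RPKM. Both have near-identical copies elsewhere in the genome, so their values are uncertain.

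**Figure D3:**
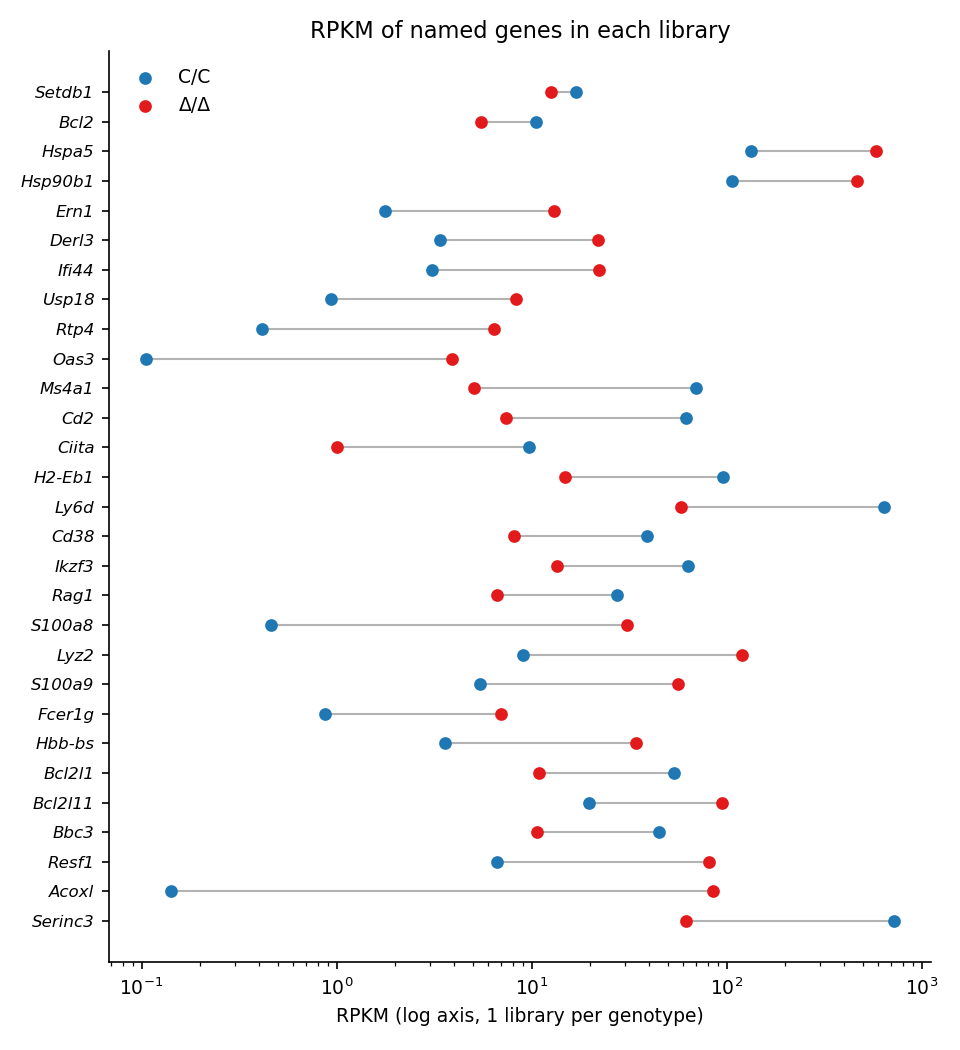
RPKM (log axis) of 29 named genes in the C/C library (blue) and the Δ/Δ library (red), 1 library per genotype. Setdb1 lies at 17.0 and 12.6 RPKM, while Hspa5 and Lyz2 lie to the right in Δ/Δ and Ms4a1, Ly6d and Serinc3 to the left.

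The libraries differed in sex-linked transcripts, with a male pattern in C/C and a female pattern in Δ/Δ. Xist, the RNA that coats the inactive X chromosome of females, measured 0.0940 RPKM in C/C and 23.7 RPKM in Δ/Δ. Of the genes on the Y chromosome, Eif2s3y (22.3 RPKM) and Uty (6.24 RPKM) were listed at 0 in Δ/Δ. Ddx3y went from 10.2 to 0.00900 RPKM, and Kdm5d, chosen after its value was seen, from 5.37 to 0.0170 RPKM. Of 329 measured protein-coding genes on the X chromosome, 12 were higher and 12 lower. On autosomes alone 743 genes were higher and 814 lower.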

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

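The test of plasma cell differentiation was chosen only after the result it addresses was seen. The others were written down before they were run, but each for a pattern whose direction was already stated, so they do not predate that pattern.

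Among transcripts that matched no gene name, 65 were at least 2-fold higher in the Δ/Δ library by the size rule. They stood out because no comparison used them. Of the 1438 measured transcripts of this kind, 80 were lower. The largest changes were ENSMUST00000118017 (0.0920 to 17.7 RPKM), ENSMUST00000174425 (0.194 to 26.1 RPKM), ENSMUST00000169170 (145 to 1.49 RPKM) and ENSMUST00000180186 (49.8 to 0.204 RPKM). What these transcripts are was not tested.

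Myeloid, dendritic and erythroid-platelet markers were higher in the Δ/Δ library. A lower share of B lineage cells would raise all other cell types alike. The median of the myeloid markers exceeded that of NK, mast cell and stromal markers by 0.81 (-0.19 to 2.84 over resampled genes). This test cannot tell an even rise from a myeloid one, because the markers pooled for comparison had unlike medians by cell type. Over members with at least 20 reads the median log2 ratios of read density were 2.87 for myeloid, 2.55 for NK, 2.99 for mast cell, 1.86 for dendritic, 1.70 for erythroid and megakaryocyte, 0.93 for T lineage and 0.58 for stromal markers. The labels describe the cells as pro-B cells sorted by flow cytometry, and whether other cells remained or grew in the culture was not tested. Activation of these genes within pro-B cells would give the same values in bulk RNA and stays open, as does an effect of the sex difference between the libraries.

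Genes of the unfolded protein response were higher in the Δ/Δ library. The list median ran from 1.53 to 1.56 under 3 other scalings, against 1.47 as deposited. All 3 raise Δ/Δ values against C/C, by a log2 shift of 0.068 for the common RPKM sum. They could only raise this median, so they cannot exclude an effect of scaling on its size. Scaling moves all genes alike, and the list lay at percentile 100 of the random lists under each. None of 5 core plasma cell transcripts was 2-fold higher. Their highest log2 ratio of read density, without the added 0.5 RPKM, was 0.09 for Jchain (interval -0.25 to 0.44). Prdm1 measured 0.558 and 0.224 RPKM, and Sdc1 12.3 and 8.02 RPKM. The others were Ighm (3274 to 1143 RPKM) and Igkc (904 to 219 RPKM), which were lower like most immunoglobulin genes. A test that asked for a rise of all 5, chosen after the values were seen, could not have come out for plasma cells. It cannot decide whether some cells differentiated to plasma cells. Other transcripts of plasma cells or secretory cells were higher by the size rule, among them Igha (0.113 to 1.13 RPKM), Zbp1 (3.04 to 7.41 RPKM), Ell2 (4.28 to 15.6 RPKM) and Bhlha15 (3.43 to 12.8 RPKM), and Cd28 measured 0.0730 and 0.246 RPKM. A stress response within the cells remains a candidate explanation, but neither protein nor the cell type that carries these transcripts was measured, and whether the quality of the RNA or libraries differed, as the higher mitochondrial and small nucleolar RNA values leave open, was not tested.

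Of 231 measured processed pseudogenes 48 were lower and 13 higher, a larger share lower (20.8%) than among coding genes (4.9%). Lower expression of the parent gene does not account for this in the class as a whole, although 4 of the 38 distinct parents were lower by the size rule. The median log2 ratio of the 38 distinct parents was -0.04 (-0.28 to 0.09 over resampled parents), where that of the lower pseudogenes was -2.03. Different placement of reads between near-identical copies might do so. The lower share among near-identical copies was 1.35 times that among the rest (0.75 to 3.25 over resampled pseudogenes), which cannot tell the explanations apart.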

How the results depend on the processing

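Every list median that stood apart in the report kept its direction under each alternative run for lists, where enough members were measured. The size rules of 1.5-fold and 4-fold and the alternatives restricted to some chromosomes or gene classes were run for gene counts only. No gene that was named by the rule and passed the size rule changed sign, and smaller changes were not checked for sign. Of 1071 pairs of a named gene and a setting, 174 moved by more than counting error. Medians ran from 1.39 to 1.56 for the unfolded protein and integrated stress response, 0.95 to 1.26 for interferon-stimulated genes, -0.59 to -0.48 for the B lineage, -1.67 to -1.52 for later B cells, 1.05 to 2.38 for myeloid, 0.44 to 2.81 for dendritic and 0.52 to 3.23 for erythroid and megakaryocyte markers. No paired analysis was possible because each genotype had 1 library. Depth limits what is seen of weak genes, and the wide intervals of Acoxl and St6galnac5 come from few C/C reads.

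The Setdb1 log2 ratio of -0.41 was -0.32 after centring, -0.35 with the common RPKM sum, -0.33 with that sum without the 20 most abundant genes, -0.35 as the mean over transcripts and -0.29 for the transcript with the most reads, always short of the size rule. With a filter of 5 RPKM, 452 genes were higher and 510 lower, because fewer genes were measured, and the zinc finger median was -0.30. Coding genes alone left 531 lower. A 1.5-fold rule gave 1583 higher and 2102 lower genes, and a 4-fold rule 220 and 234, against 788 and 836. The p53 and apoptosis median was -0.34 with a pseudocount of 0.1 RPKM, and the IL-7 median was -0.31 with a pseudocount of 1 RPKM and -0.25 with the common RPKM sum. Both lists stood apart under these settings only. Without a filter, medians were -0.079 for genes of retroviral origin and -0.022 for stem cell markers, which no longer stood apart, and 0.26 for T lineage markers, which then did. Apart from the filter and the size rule, the cause was not tested.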

Other observations

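The test of neighbouring genes below was chosen only after the values were seen, and so were the genes named in this part.

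Single genes of the secretory pathway outside the fixed list, picked because they were higher, were as follows. Sec24d, a coat protein of vesicles that leave the endoplasmic reticulum, measured 3.45 RPKM in C/C and 24.6 RPKM in Δ/Δ, 7.14-fold more (interval 6.71 to 7.59). The translocon genes Sec61b (160 to 449 RPKM) and Sec61g (117 to 399 RPKM), the translocon-associated gene Ssr3 (23.6 to 73.2 RPKM) and the signal peptidase gene Spcs3 (10.8 to 35.5 RPKM) were higher too. So were Creb3l2 (1.44 to 9.89 RPKM), a membrane-bound transcription factor of secretory cells, and Bhlha15 (Mist1, 3.43 to 12.8 RPKM), a target of XBP1. Interferon-induced genes picked in the same way were the GTPase genes Iigp1 (0.0800 to 4.40 RPKM) and Gbp7 (11.7 to 56.6 RPKM), Ifitm3 (10.5 to 44.7 RPKM), which blocks virus entry, and the inflammatory caspase gene Casp4 (6.48 to 33.2 RPKM).

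Intergenic non-coding RNA genes without a proper name were among the strongest increases at high level. Gm26809 on chromosome 6 measured 36.1 RPKM in C/C and 771 RPKM in Δ/Δ, and on chromosome 4 Gm26880 went from 16.8 to 519 RPKM and Gm12840 from 8.56 to 321 RPKM. Of 198 measured genes of this class 23 were higher and 11 lower. The RNase P RNA gene Rpph1 measured 7673 and 17221 RPKM, the opposite direction to its relative Rprl3. Motifs of retroviral proteins were sought in all 89571 named transcripts and found in 7, of which 3 were measured. D10Wsu102e carried them on the opposite strand and was higher (9.99 to 26.8 RPKM). Its transcript holds 123179 exonic bases, so its RPKM does not tell whether the stretch with the motifs was higher. The motif-bearing transcripts of Brip1os (17.6 and 13.5 RPKM) and Foxn2 (3.04 and 3.38 RPKM) were within the size rule.

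Loss of a silencing enzyme could release neighbouring genes together, and the data were consistent with shared changes among neighbours. Of 8748 adjacent pairs of coding genes without similar symbols or proteins 46 were both higher, against a median of 25 and a maximum of 45 in shuffled orders. Adjacent here means without another measured coding gene between them, and the gap of the 46 pairs had a median of 70486 bases and a maximum of 2719128 bases. Acoxl and Bcl2l11 are such a pair, and Txnrd1, Chst11, Slc41a2 and D10Wsu102e are a run on chromosome 10. Lower pairs were in excess as well (49 against 21), so the excess is not special to raised genes, and some related genes, such as Mt1 and Mt2, escaped the exclusion.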
